A study of Acetonema longum with 18 samples.

How the data were processed

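RNA was measured by sequencing in Acetonema longum strain APO-1, an anaerobic spore-forming bacterium of the Firmicutes whose cells carry an outer membrane (a diderm). Per the labels, exponential phase stands for 3-day subcultures and stationary phase for 5-day subculture material, the stage that the series design calls sporulation. Germination stands for purified spores heat shocked at 60 °C for 15 min and collected 16 hours after inoculation. There were 7 exponential, 6 stationary and 5 germination libraries. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

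The libraries were made in 2 batches, per the labels' protocols. The 2021 batch (5 exponential and 4 stationary libraries) used Ribo-Zero to remove ribosomal RNA and the KAPA RNA HyperPrep library kit. The 2023 batch (2 exponential, 2 stationary and all 5 germination libraries) used the NEBNext bacterial depletion and Ultra II Directional kits. Batch is thus crossed with exponential and stationary phase, while germination was measured in 2023 alone.

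The deposited values are raw read counts per gene, not normalised, in a table of 4174 features on 276 contigs with start, end, strand and length. The submitters' processing notes name cutadapt 2.3, STAR 2.7.10b and featureCounts 2.0.1. The genome build and the strand setting of the counting are not given in the sources used here, so counts of overlapping genes and of genes on opposite strands are uncertain. Each library's column was taken from the label that names it, and 1 count column that no label names was not used. Coordinates are those of the table, and contigs are numbered by the last digits of their names in it. The table pairs its locus tags with no gene names, and no annotation was used here. The 22 gene lists chosen beforehand (among them outer membrane assembly, lipopolysaccharide, sporulation and germination genes) could therefore not be matched to features, and neither their counts nor their set tests were run.

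Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features with too few counts were removed with filterByExpr by stage, which left 4064 features tested. Library sizes were scaled with TMM factors, and the quasi-likelihood test (glmQLFit and glmQLFTest, robust) was fitted to all 18 libraries with terms for batch and stage. Adjusted p-values are Benjamini-Hochberg values over all features tested in a comparison, and a gene was called changed below 0.05. The biological coefficient of variation of the common dispersion was 0.336. Levels are CPM after TMM scaling (normalised CPM), and SE is the log2 fold change divided by the square root of its F statistic. Where all libraries of a group in 2023 held 0 counts, a fold is given against 3 counts over the group, and where they held 1 to 3 counts, the ratio carries an exact 95% interval that covers counting error only.

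Sequencing depth ranged from 9397550 to 18049932 counts per library, but 3 features took most of the counts in several 2023 libraries. These dominant features were defined after the data were seen, as features above 2% of the counts in every exponential and stationary library of 2023. The counts outside them, 520524 to 15124299, set the precision of all other genes. Among pairs of replicates, the lowest chi-square per degree of freedom was 2.81, between exponential replicates 6 and 7, then 3.25 between stationary replicates 5 and 6. It was scaled over all features, the dominant ones included. It therefore does not settle whether the other genes of these pairs differed beyond sampling noise.

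Before the data were examined, the tests, the alternatives and the rule for named genes were fixed. Without gene names the rule takes, per comparison, the 2 genes with the highest and the 2 with the lowest log2 fold change among genes past the threshold with a mean of at least 10 normalised CPM over the libraries compared. Regions were added after the data were seen. A region is a run of at least 3 neighbouring genes on 1 strand, at most 100 bases apart, that all passed the threshold in the same direction with an absolute log2 fold change of at least 1. Named regions have at least 4 genes and a mean of at least 10 normalised CPM, and are the 2 with the largest mean change and the longest one per direction. The number of genes in runs was compared with 1000 shuffles of the fold changes among genes. The stage-by-batch interaction was tested with the same tool on the 13 exponential and stationary libraries.

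The fitting code was tested on simulated counts drawn with these libraries' batch means, sizes and dispersions, with 100 genes changed by each fold. In the simulated stationary against exponential comparison, run on 4057 genes, it recovered 71% of 2-fold and 98% of 4-fold changes with 9 false calls. For germination against exponential phase, run on 4056 genes, recovery was 44% and 85% with 8 false calls. For germination against stationary phase, also on 4056 genes, it was 44% and 84% with 12 false calls. All other simulated genes were unchanged, while most genes passed in each real comparison. The simulation therefore does not test the scaling or the error rate under such broad change.

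The alternatives were RLE size factors, library totals alone, DESeq2 1.42.0, no low-count filter, a filter of 5 CPM in 5 libraries, no batch term, each batch alone, the compared stages alone, the replicate number as a block, a test against a log2 fold change of 1 (glmTreat), and each library left out. The removal of structural RNA genes, planned beforehand, needed gene names; removing the 3 dominant features took its place. Also added after the data were seen were thinning every library to equal counts outside the dominant features and leaving out both 2023 exponential libraries.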

Results

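The series profiled A. longum through its sporulation cycle, and its title concerns the outer membrane protein BamA in the remodelling of inner into outer membrane in diderm Firmicutes. The comparisons the design implies are stationary phase (sporulating cultures) against exponential phase (vegetative growth), germinating spores against exponential phase, and germinating spores against stationary phase. Genes are given by locus tag with their contig and position, because the count table does not pair the tags with names; the gene for BamA was not analysed here.

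Total counts per library were 14999100 ± 1813740 in exponential phase (SD, n = 7), 14092800 ± 1966570 in stationary phase (SD, n = 6) and 13792700 ± 2728350 in germination (SD, n = 5). Outside the 3 dominant features, the 2021 libraries held 12067026 to 15124299 counts. The 2023 exponential libraries held 520524 and 633765, and the 2023 stationary libraries 1012811 and 1357251. Germination libraries held 2661364 to 13229568. The median count per gene was 590 to 871 in the 2021 libraries, 24 and 29 in the 2023 exponential libraries, 63 and 82 in the 2023 stationary libraries and 121 to 648 in germination. Values from the 2023 exponential libraries therefore carry the largest counting error.

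**Figure D1:**
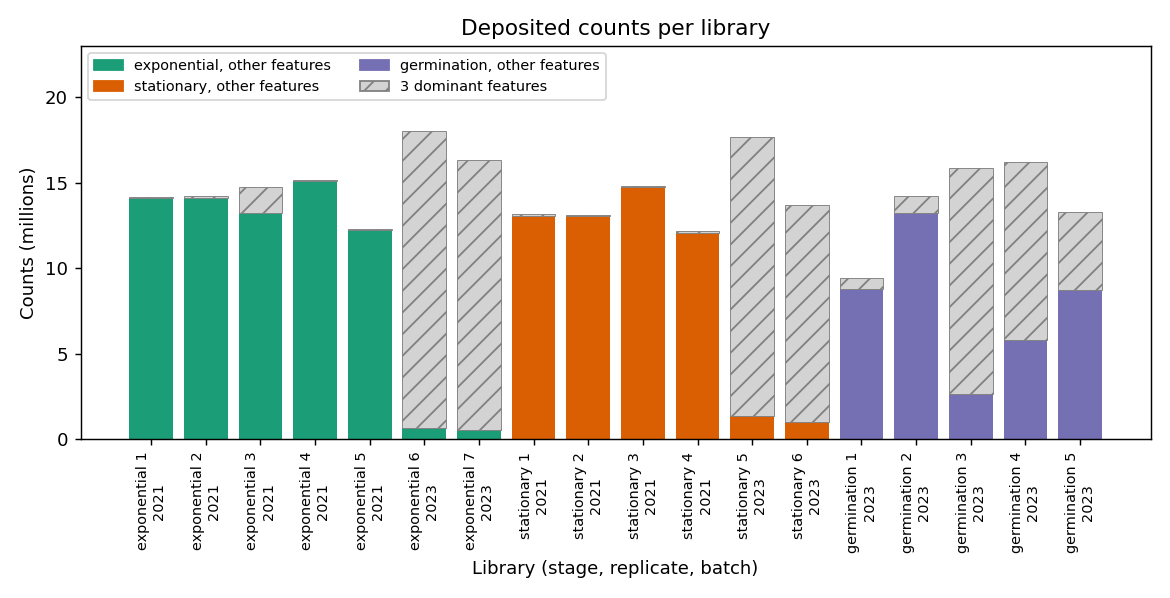
Deposited counts per library (bars from 0), split into the 3 dominant features (hatched) and all other features (coloured by stage); labels below give stage, replicate and batch. The dominant features take over 92% of the counts in the 4 exponential and stationary libraries of 2023 and 6.73% to 83.2% in germination.

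Libraries grouped by stage. The first principal component of log2 normalised CPM held 42.3% of the variance and set the germination libraries, at scores of 71.8 to 77.8, apart from the exponential and stationary libraries, at -42.2 to -16.6. The second, with 25.5%, separated stationary libraries (38.6 to 54.1) from exponential libraries (-43.6 to -24.1). The third, with 12.1%, separated the batches within exponential and stationary phase. Within germination, all of 2023, it was at 7.2 and 7.4 where the dominant features held 6.73% and 7.07% of the counts. It was at -8.7 where they held 83.2%. In exponential and stationary phase that share changed with the batch, so this component does not tell batch from counts outside the dominant features. The median Spearman correlation across genes, which are not independent replicates, was 0.988 within germination, 0.965 within a batch in exponential phase and 0.961 within a batch in stationary phase. Between batches it was 0.922 in exponential and 0.931 in stationary phase. It fell by stage to 0.837 between exponential and stationary, 0.785 between germination and stationary, and 0.768 between germination and exponential libraries.

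**Figure D2:**
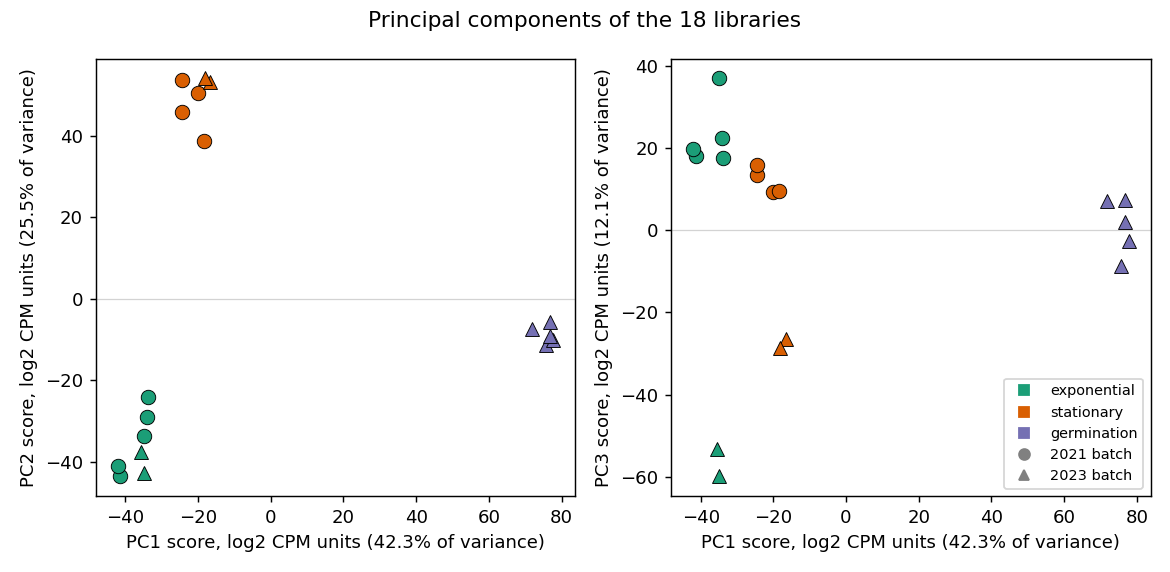
Principal component scores of the 18 libraries from log2 normalised CPM, component 1 against 2 (left) and against 3 (right); colour gives the stage and marker shape the batch. Component 1 sets germination apart, and component 2 separates exponential from stationary libraries. Component 3 separates the batches within exponential and stationary phase, with the germination libraries, all of 2023, between them at -8.7 to 7.4. The lowest of these is the germination library with the largest share of dominant features (83.2%).

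Between exponential and stationary phase, the largest mean fall among the named regions was in 6 adjacent minus-strand genes on contig 24 (7285 to 13117). Their mean level was 343 ± 251 normalised CPM in exponential phase (SD, n = 7) and 0.720 ± 0.336 in stationary phase (SD, n = 6), with log2 fold changes of -9.90 to -7.30 and a mean of -8.96. A run of 7 plus-strand genes on contig 17 (79656 to 85502) rose from 4.35 ± 8.26 to 88.7 ± 54.2 normalised CPM, a mean log2 fold change of 5.65. On contig 19 (20083 to 28089), 7 minus-strand genes rose from 1.53 ± 1.14 to 53.0 ± 72.0, a mean of 5.10. Within the batches, the means were -8.91 (2021) and -9.45 (2023) for contig 24, 5.62 and 6.72 for contig 17, where not every gene passed in 2021 alone, and 5.09 and 5.49 for contig 19. The libraries of each batch are part of those that chose the regions. Every gene of a region passed the threshold by definition, so that is no separate support. The highest adjusted p in these 3 regions was 9.20e-07, 0.0139 and 0.000595 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). On contig 19, 4 of 6 stationary libraries lay above all exponential libraries; replicates 1 and 4, at 2.23 and 2.17 normalised CPM, lay below exponential replicate 5 at 4.02. Its mean was 3.80 without stationary replicate 3 (at 192 normalised CPM) and 5.71 without exponential replicate 5. On contig 17, exponential replicate 2 was at 23.02 and the others at 0.497 to 2.34; the mean was 6.47 without it, and 3.56 with 2 of 7 genes passing when libraries were thinned to equal depth. Thinning left 1 of 7 genes passing on contig 19, with a mean of 5.41.

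The longest named runs changed less. On contig 79 (16231 to 26499), 11 plus-strand genes rose from 6.38 ± 1.38 normalised CPM in exponential phase (SD, n = 7) to 18.5 ± 10.5 in stationary phase (SD, n = 6), a mean log2 fold change of 1.61. The rise was in 4 of 6 stationary libraries, with replicates 1 and 4 at 5.34 and 6.17 inside the exponential range of 4.83 to 8.68. On contig 101 (3268 to 9465), 8 minus-strand genes fell from 97.7 ± 37.7 to 21.4 ± 4.48, a mean of -2.13. The means were 1.52 (2021) and 2.10 (2023) for contig 79, where 6 of 11 genes passed in 2023 alone, and -2.47 and -1.22 for contig 101, where 7 of 8 did. Not every gene of the contig 79 run still passed without exponential replicate 5, stationary replicate 2 or stationary replicate 3, with means of 1.63, 1.50 and 1.07. A further run of 7 minus-strand genes on contig 10 (199 to 6735) had a mean log2 fold change of -5.57, but the batches differed. It was -6.03 in 2021 and -1.56 in 2023, where 1 of 5 genes tested passed, and the 7 exponential libraries ranged from 7.33 to 466 normalised CPM against 1.29 to 4.55 in the stationary libraries. Without exponential replicate 2, at 466, the mean was -4.29, and thinned to equal depth it was -7.29 with 1 gene passing.

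Among single genes, ALO_RS09875 (contig 81, 76715 to 76978, plus strand) rose from 2.85 ± 2.02 normalised CPM in exponential phase (SD, n = 7) to 361 ± 252 in stationary phase (SD, n = 6). Its log2 fold change was 7.02 ± 0.58 (SE; adjusted p = 6.17e-08, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with 7.02 in the 2021 and 7.07 in the 2023 libraries. ALO_RS02435 (contig 17, 83366 to 84094), inside the contig 17 run, rose by 6.81 ± 0.48 on the log2 scale (edgeR adjusted p = 5.37e-09), and by 7.62 without exponential replicate 5. It was 6.73 in 2021, and in 2023 both exponential libraries held 0 counts, so that the level in stationary phase was at least 21-fold higher. ALO_RS03560 (contig 24, 10861 to 12459) had a log2 fold change of -9.90 ± 0.80 (edgeR adjusted p = 5.45e-08) and -9.93 in 2021. With 687 against 2 counts, the exponential level in 2023 was 889-fold the stationary level (interval 245 to 7353). ALO_RS03565 (contig 24, 12482 to 13117) had -9.47 ± 0.98 (edgeR adjusted p = 9.20e-07), -9.59 in 2021 and a ratio of 288 in 2023 (79 to 2397). All 6 stationary libraries lay beyond all 7 exponential libraries for each of these 4 genes.

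Of 4064 genes tested with edgeR's quasi-likelihood test, 1260 were higher and 1232 lower in stationary phase, 61.3% in all. At least 2-fold changes numbered 628 higher and 706 lower, and at least 8-fold changes 90 higher and 87 lower. The 2021 libraries alone gave 992 higher and 985 lower of 4049, and the 2023 libraries alone, with 2 against 2, gave 755 higher and 664 lower of 4002. Of 1952 genes called in 2021 and tested in both batches, 1033 were also called in 2023, 1028 in the same direction and 5 in the opposite. Fold changes of the batches correlated across genes, which are not independent replicates, at a Pearson r of 0.643. With library totals in place of TMM factors, 1617 genes passed and 82.2% of them were higher. The dominant features then enter the scale, but whether they alone made this difference was not tested. The median log2 fold change of all genes was -0.02 with TMM and 0.60 with totals.

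**Figure D3:**
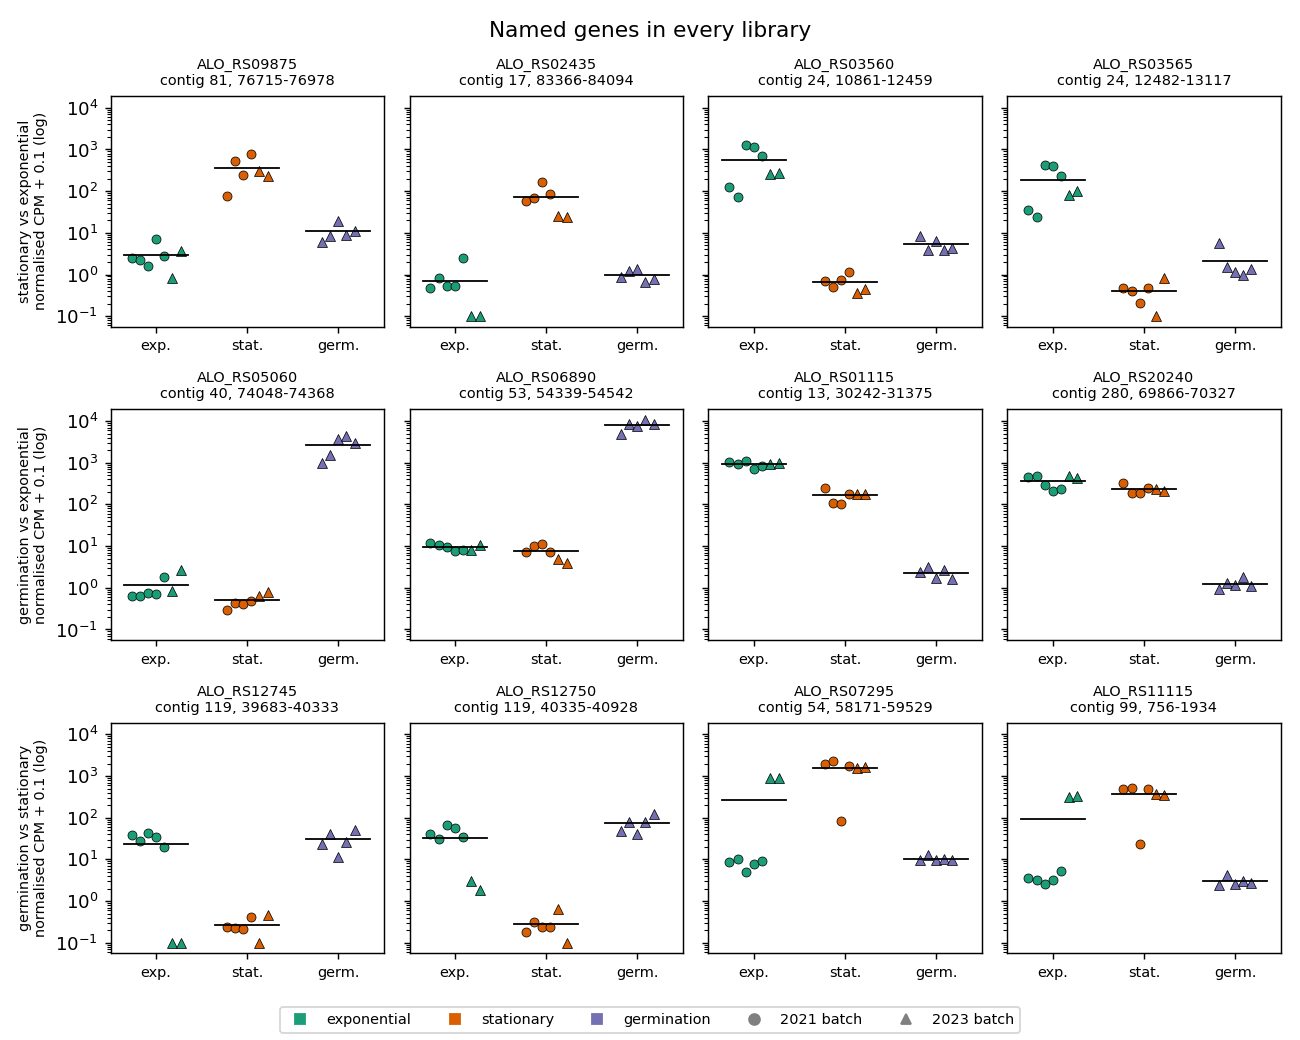
Normalised CPM plus 0.1 on a log axis for the 12 named genes (1 row per comparison); points are libraries (circles 2021, triangles 2023) and black lines the mean of a stage. For ALO_RS07295 and ALO_RS11115 the exponential libraries split by batch, and stationary replicate 3 lies below the other stationary libraries.

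Germinating spores differed from exponential cells most, among the named regions, in 4 plus-strand genes on contig 234 (91664 to 95472). These rose from 4.49 ± 0.571 normalised CPM in exponential phase (SD, n = 7) to 1117 ± 183 in germination (SD, n = 5), with log2 fold changes of 7.21 to 8.62 and a mean of 8.11. On contig 84 (13955 to 17611), 4 plus-strand genes rose from 26.3 ± 9.53 to 702 ± 172, a mean of 5.18. A run of 11 plus-strand genes elsewhere on contig 234 (52389 to 63940) rose from 13.2 ± 2.99 to 118 ± 8.41, a mean of 3.28. The contig 24 genes that fell in stationary phase were also lower in germination, at 3.73 ± 0.707 normalised CPM, a mean of -6.11. On contig 144 (23903 to 34028), 10 plus-strand genes fell from 16.6 ± 5.48 to 0.818 ± 0.265, a mean of -5.11.

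By the definition of a region, all genes of these 5 passed edgeR's quasi-likelihood test. The highest Benjamini-Hochberg adjusted p over them was 0.000102. With the replicate block 0 of 6 contig 24 genes passed (mean -3.82), and with library totals 4 did (-2.06). On contig 144, 6 of 10 passed with library totals (-1.49). Among the 2023 libraries alone, in the order of the regions above, the means were 7.71, 5.46, 3.17, -6.19 and -4.93. All tested members passed there (9 of 10 genes on contig 144 could be tested), but these libraries also took part in choosing the regions. A run of 4 minus-strand genes on contig 99 (16 to 3206) was named by the same rule, with a mean of -5.62, yet it rested on the 2023 exponential libraries. The level was 225 ± 4.29 normalised CPM there (SD, n = 2), 2.23 ± 0.433 in the 2021 exponential libraries (SD, n = 5) and 2.23 ± 0.512 in germination (SD, n = 5). Without the 2023 exponential libraries the mean was -0.54 for contig 99, where 0 of 4 genes passed, and -5.73 for contig 24, where 1 of 6 did.

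**Figure D4:**
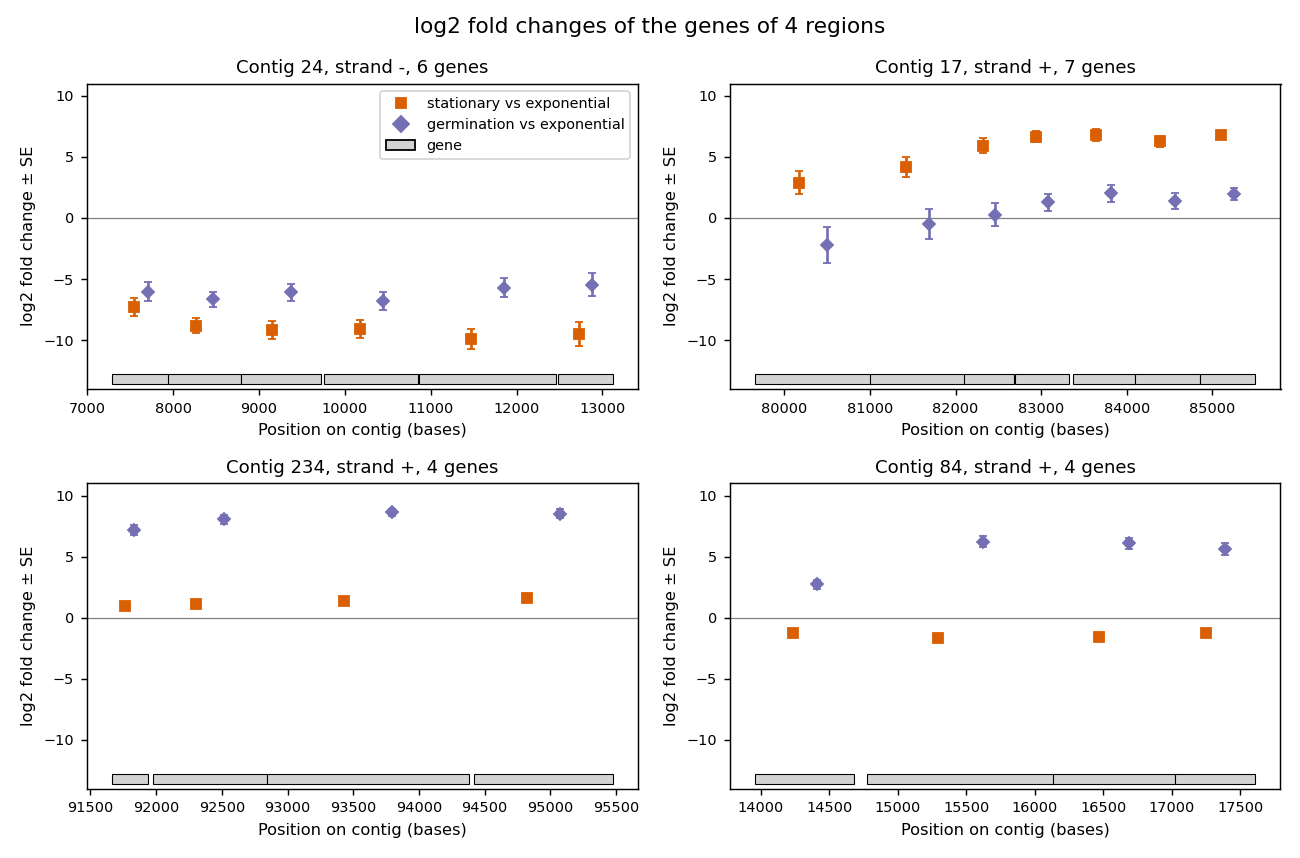
Log2 fold change with SE (bars) of each gene in 4 regions against its position on the contig in bases, for stationary (squares) and germination (diamonds) against exponential phase; grey boxes are the genes. Contig 24 genes lie below 0 in both comparisons, contig 17 genes rise in stationary phase, and the contig 234 and 84 genes rise in germination.

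ALO_RS05060 (contig 40, 74048 to 74368, plus strand) had the largest rise among the genes eligible to be named, from 1.05 ± 0.80 normalised CPM in exponential phase (SD, n = 7) to 2703 ± 1410 in germination (SD, n = 5). Its log2 fold change was 10.71 ± 0.68 (SE; adjusted p = 1.28e-10, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and 10.72 among the 2023 libraries. ALO_RS06890 (contig 53, 54339 to 54542, plus strand) rose from 9.44 ± 1.73 to 8057 ± 2115, by 10.19 ± 0.40 on the log2 scale (edgeR adjusted p = 1.79e-13; 9.78 in 2023). ALO_RS01115 (contig 13, 30242 to 31375, minus strand) fell from 937 ± 120 to 2.22 ± 0.688, a log2 fold change of -8.75 ± 0.34 (edgeR adjusted p = 1.75e-13; -8.70 in 2023). ALO_RS20240 (contig 280, 69866 to 70327, minus strand) fell from 372 ± 119 to 1.16 ± 0.329, a log2 fold change of -8.45 ± 0.35 (edgeR adjusted p = 4.53e-13; -8.62 in 2023). For each of these 4 genes all 5 germination libraries lay beyond all 7 exponential libraries.

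Germination against exponential phase gave 1322 higher and 1142 lower genes of 4064 with edgeR's quasi-likelihood test, 60.6% in all. At least 2-fold changes numbered 984 higher and 891 lower, and at least 8-fold changes 199 higher and 220 lower. The 2023 libraries alone, in which both stages shared kits, gave 1371 higher and 1153 lower of 4002. With library totals in place of TMM factors, 3687 genes passed, 98.3% of them higher, and 804 genes called with both scalings changed direction. The median log2 fold change of all genes moved from 0.10 to 3.77, so directions in this comparison are relative to the bulk of genes.

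Against stationary phase, the same contig 234 region (91664 to 95472) stood 6.82 higher in germination on the log2 scale, at 1117 ± 183 against 11.3 ± 3.90 normalised CPM (SD, n = 5 and n = 6). The contig 84 region stood 6.59 higher, with 702 ± 172 against 11.0 ± 2.27, and the 11-gene run of contig 234 stood 2.27 higher, with 118 ± 8.41 against 24.4 ± 3.38. On contig 269 (7718 to 15578), 11 plus-strand genes fell from 138 ± 10.8 normalised CPM in stationary phase to 19.4 ± 1.03 in germination, a mean log2 fold change of -3.75. On contig 270 (5765 to 8747), 4 plus-strand genes fell from 21.02 ± 20.9 to 0.70 ± 0.103, a mean of -5.31; 5 of 6 stationary libraries lay above all germination libraries, and the range was 0.520 to 48.9. The contig 99 region fell from 226 ± 105 to 2.23 ± 0.512, with a mean of -10.67 in the fit of all libraries (-11.80 without stationary replicate 5 or 6) and -6.79 among the 2023 libraries. Every gene of the 6 regions passed edgeR's quasi-likelihood test by definition, with a highest Benjamini-Hochberg adjusted p of 0.000521. All passed among the 2023 libraries too, which took part in choosing the regions. On contig 270, 2 of 4 genes passed with library totals (mean -2.29) and 2 with the replicate block (-4.28).

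The 4 genes named in this comparison also had larger folds in the fit of all libraries than in 2023 alone. This is because their batch difference in exponential phase enters the batch term, while germination was measured in 2023 alone. The rule that named them ranked these larger folds. In 2023, ALO_RS05060 was at 2703 normalised CPM in germination and 0.620 in stationary phase (2 counts per library), and ALO_RS06890 at 8057 and 4.34. By these means both rose more within 2023 than the 2 genes named as higher. The wide intervals of the 2023 ratios of those 2 genes, given below, leave the order uncertain. ALO_RS12745 (contig 119, 39683 to 40333, minus strand) was at 30.6 ± 15.8 normalised CPM in germination (SD, n = 5) and 0.174 ± 0.135 in stationary phase (SD, n = 6). Its log2 fold change was 13.52 ± 1.04 (SE; edgeR quasi-likelihood adjusted p = 3.88e-09) with all libraries, where both 2023 exponential libraries, which enter the batch term, hold 0 counts. It was 12.26 and 12.53 without exponential replicates 6 and 7, and 18.60 without stationary replicate 6, where the 2023 stationary count is also 0 and the value is no usable fold. In 2023 it had 3100 counts in germination against 1 in stationary phase, a ratio of 229 (interval 41.1 to 9055). Its neighbour ALO_RS12750 (contig 119, 40335 to 40928) was at 74.1 ± 32.7 against 0.186 ± 0.185, with 12.46 ± 0.82 (edgeR adjusted p = 4.70e-10) and a 2023 ratio of 260 (71.9 to 2146); it was 11.82 without exponential replicate 7 and 13.16 without stationary replicate 5. ALO_RS07295 (contig 54, 58171 to 59529, minus strand) fell from 1560 ± 775 to 10.2 ± 1.30, a log2 fold change of -11.76 ± 1.62 (edgeR adjusted p = 1.15e-05) and -7.30 ± 0.14 in 2023. ALO_RS11115 (contig 99, 756 to 1934), which overlaps the gene before it, fell from 370 ± 183 to 2.89 ± 0.711, with -11.20 ± 1.58 (edgeR adjusted p = 1.42e-05) and -6.90 ± 0.18 in 2023. Without stationary replicate 5 or 6 the fit of all libraries gave -12.87 and -12.32 for these 2 genes. All 5 germination libraries lay beyond all 6 stationary libraries for each gene.

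In total 1291 genes were higher and 1140 lower in germination than in stationary phase, 59.8% of 4064 by edgeR's quasi-likelihood test. At least 2-fold changes numbered 898 higher and 829 lower, and at least 8-fold changes 210 higher and 217 lower. The 2023 libraries alone gave 1416 higher and 1226 lower of 4002. With library totals 3669 genes passed, 97.7% of them higher, 731 called with both scalings changed direction, and the median log2 fold change was 3.21 against 0.11.

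Genes were also sorted by the stage that differed from both others. Germination stood highest for 933 genes and lowest for 777, exponential phase highest for 589 and lowest for 677, and stationary phase highest for 471 and lowest for 473. Differences of at least 8-fold from both other stages numbered 106 and 101 for germination, 41 and 16 for exponential phase, and 55 and 34 for stationary phase, higher and lower in turn. Each set joins 2 comparisons that share libraries. Unchanged simulated groups gave 0 such genes in 20 simulations. No gene differed between stages there, so this does not measure the overlap that shared libraries give among changed genes. With the shared libraries split between the 2 comparisons, the counts were 792 and 648 for germination, 512 and 572 for exponential phase, and 346 and 337 for stationary phase. Independent lists of the sizes called in those split fits would share 323 and 230 genes for germination, 269 and 328 for exponential phase, and 269 and 282 for stationary phase. The 2023 libraries alone gave 1024 and 796 for germination, 453 and 471 for exponential phase, and 379 and 258 for stationary phase.

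Changed genes lay next to each other on the contigs. Runs held 514 genes in the stationary against exponential comparison (63 runs higher and 59 lower), 557 in germination against exponential phase (70 and 65) and 541 in germination against stationary phase (64 and 62). Shuffling the fold changes among genes gave means of 24.9, 67.8 and 53.2 genes in runs (one-sided permutation p = 0.000999 in each comparison, the smallest that 1000 shuffles can give).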

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

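The tests of the batch difference and of the dominant features in this part were chosen after those results were seen; the interaction test itself was planned.

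For 51 genes on 26 contigs, the difference between stationary and exponential phase itself differed between the batches (interaction term, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 13 libraries, 3978 genes tested). The signed log2 value, stationary minus exponential, was higher in 2023 than in 2021 for 38 of them and lower for 13, whatever the size of the stage difference. On contig 99 (16 to 3206), 4 genes were at 2.23 ± 0.433 normalised CPM in the 2021 exponential libraries (SD, n = 5) and 225 ± 4.29 in those of 2023 (SD, n = 2). Stationary phase was at 210 ± 132 in 2021 (SD, n = 4) and 258 ± 0.938 in 2023 (SD, n = 2); stationary replicate 3 was at 15.2 and the other 2021 stationary libraries at 254 to 306. The named genes ALO_RS07295 and ALO_RS11115 moved likewise, with interaction terms of -6.71 and -6.57 on the log2 scale (edgeR adjusted p = 0.0337 for each). On contig 17 (59335 to 65335), 5 genes rose only in the 2023 stationary libraries, to 161 ± 17.3 against 22.4 ± 5.92 in those of 2021 (SD, n = 2 and n = 4). On contig 162 (10429 to 14195), 4 genes were at 21.96 ± 4.23 in exponential phase in 2021 and 3.51 ± 0.359 in 2023. The number rests on few libraries: it was 31 without exponential replicate 1, 25 without exponential replicate 3, 7 without exponential replicate 6 and 11 without exponential replicate 7. It was 30, 25, 12 and 14 without stationary replicates 1, 2, 5 and 6.

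Low counts in the 2023 exponential libraries would give each library its own counting error. The 51 genes ranked first with 1 of these libraries left out were therefore estimated again with the other left out; the 2 fits share all other libraries. The median ratio of the second difference to the first was 0.999 with genes ranked on exponential replicate 6 (lower quartile 0.821, same sign in 50 of 51) and 0.870 with replicate 7 (0.758, 49 of 51). The differences were thus similar whichever of the 2 libraries was used. Genes ranked partly on the shared libraries keep part of their difference in both fits, even where counting error is the cause. The ratio that low counts would give was not computed, so this test does not decide on low counts. With all libraries thinned to equal depth, 36 of the 51 genes could be tested and 34 passed in the same direction. Thinning removes differences in depth but not the counting error of the 2023 exponential libraries, so it does not test low counts there. Stationary-phase cells mixed into the 2023 exponential cultures would carry in all abundant stationary transcripts. The 8 interaction genes that were at least 8-fold higher in stationary phase in 2021, with a smaller difference in 2023, were chosen partly for a high level there and stood at a median of 68.3% of their 2023 stationary level in the 2023 exponential libraries (quartiles 53.2% and 93.7%). All 62 genes at least 8-fold higher in stationary phase in 2021, the 8 included, with at least 30 counts in the 2023 stationary libraries, stood at a median of 4.12% (1.07% and 12.2%), and 6 reached 50%. That argues against an admixture large enough to raise the 8; the other interaction genes are not covered by this test. A kit effect that shifts a gene alike in every library would cancel in the interaction term. Genes chosen by that term must shift unequally, so the values of contigs 99 and 162 describe the pattern and are no test of such an effect. On contig 99 exponential phase moved from 2.23 to 225 while stationary phase was at 210 (254 to 306 apart from replicate 3) and 258, and germination, made with the 2023 kits, was at 2.23. On contig 162 exponential phase fell from 21.96 to 3.51 while stationary phase stayed at 3.38 and 4.00 and germination was at 18.3. Open and untested are a kit effect that depends on the RNA of a stage, a difference in how the cultures grew or when they were collected, and a change in the strain between the years. No biological explanation was tested.

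In 2 named genes, single libraries stood far from the others of their stage. Stationary replicate 3 was at 82.2 normalised CPM for ALO_RS07295 and 23.9 for ALO_RS11115, where the gap to the next library was 0.886 and 0.869 of the whole log2 range. As a set, the 8 genes above had a geometric mean of 35.4 in stationary replicate 3 against 399 to 472 in the other 5 stationary libraries. ALO_RS15260 on contig 163, 1 of the 8, was at 216 there and did not share the fall. Germination replicate 2 was at 12.5 for ALO_RS07295, with a gap ratio of 0.750. With 30 groups examined, chance gives about 1.5 such libraries, and 3 were found, 2 of them from genes that change together. When single libraries were left out, the log2 fold change between germination and stationary phase in the fit of all libraries ranged from -12.87 to -11.28 for ALO_RS07295 and from -12.32 to -10.69 for ALO_RS11115.

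The 3 dominant features lie at contig 276 (7 to 2949, 2943 bases), contig 106 (1 to 1551, 1551 bases) and contig 293 (229 to 340, 112 bases). Their summed share of the counts was 92.3% to 96.8% in the 2023 exponential and stationary libraries and 0.0907% to 10.6% in those of 2021, with 81.8 percentage points between the lowest of the former and the highest of the latter. Growth stage cannot account for this, since stationary phase held at most 0.640% in 2021 and at least 92.3% in 2023. The batch of library processing may account for it, as the depletion kit changed with the batch; the lengths would fit ribosomal RNA genes, which could not be looked up without an annotation. Batch alone leaves the germination libraries unexplained: 2 of the 5 (6.73% and 7.07%) lay below the highest 2021 library, and the others were at 34.3%, 64.1% and 83.2%, all in 2023. How much of the spread among germination libraries came from depletion or from the RNA was not tested.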

How the results depend on the processing

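Across 32 settings, no named gene or region reversed, while the balance of higher and lower counts did turn. Germination against exponential phase had 1322 higher and 1142 lower genes. Of its calls, 49.3% were higher with RLE factors, 49.0% with DESeq2, 48.4% without a batch term and 48.6% with the replicate block. Against stationary phase (1291 and 1140) these shares were 49.5%, 49.0%, 47.1% and 47.4%. With library totals 804 and 731 called genes changed direction. All 375 values of the 12 named genes kept their direction and stayed past the threshold. These genes were chosen for the largest folds in the same libraries, so that is no separate support. ALO_RS02435 could not be tested when libraries were thinned to equal depth. The log2 fold change of ALO_RS12745 ranged from 7.44 without a batch term to 18.60 without stationary replicate 6. The latter value rests on 0 counts and is no fold. Of 564 region values, 527 stayed past the threshold for every gene, and in 37, over 11 results, at least 1 gene missed it or could not be tested. All genes missed it in 4 of these, in germination against exponential phase: contig 24 with the replicate block (-3.82, against -6.11), and contig 99 with library totals (-1.43), with the replicate block (-1.87) and without the 2023 exponential libraries (-0.54). Of 186 values of the stage sets, 165 stayed within 1.5 times the count reported and 21 moved further: all 6 sets with library totals, the replicate block and the log2 fold threshold, 2 when thinned and 1 in 2023 alone. With library totals the sets higher and lower were 3419 and 33 (germination), 27 and 1252 (exponential phase) and 48 and 263 (stationary phase). Of 204 values of gene counts, 178 stayed within 1.5 times the count reported.

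Counts moved further in these settings. With library totals alone, stationary against exponential phase had 288 lower genes. Germination against exponential phase had 3626 higher and 61 lower, and germination against stationary phase 3586 higher and 83 lower. The dominant features enter this scale, but whether they alone moved the counts was not tested. The 2023 libraries alone gave 755 higher and 664 lower in stationary phase. They had both fewer samples and fewer counts per gene, and which of these mattered was not tested. Testing against a log2 fold change of 1 gave 305 and 369, 645 and 598, and 588 and 569 in the same order, by construction. A replicate block with the batch term gave 624 and 659 for germination against exponential phase and 650 and 721 against stationary phase. The numbers do not pair the samples: residuals of the 16 pairs with the same number correlated at -0.0838 to 0.151, and 3 of 18 libraries correlated best with their own number. Interaction genes numbered 97 with DESeq2 (the cause was not tested) and 7 to 50 when single libraries were left out. Thinned to equal counts outside the dominant features, 2991 genes could be tested in stationary against exponential phase, with 879 higher and 885 lower. Fewer genes of low regions could then be tested, and those passing were 4 of 11 on contig 79, 6 of 10 on contig 144 and 1 of 4 on contig 270, beside the regions of contigs 10, 17 and 19 given above. The other counts ranged, when single libraries were left out, from 1170 to 1255 higher and 1125 to 1308 lower (stationary against exponential), 1126 to 1396 and 1101 to 1243 (germination against exponential), and 1076 to 1335 and 1076 to 1186 (germination against stationary). The set tests of the gene lists and the removal of structural RNA genes were not run, since both need gene names.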

Other observations

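Of the tests in this part, the 1 for shared reads was chosen after the results were seen; those of strand and of other splits of the samples were planned.

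Exponential libraries differed among themselves in some regions. The contig 24 genes (7285 to 13117) were at 83.4, 50.5, 721, 597, 412, 254 and 286 normalised CPM in exponential replicates 1 to 7. The contig 10 genes (199 to 6735) were at 207, 466, 16.4, 9.05, 39.4, 22.05 and 7.33 in the same libraries. Longer genes had somewhat higher log2 fold changes in germination: the median was -0.15 for genes of 63 to 480 bases and 0.26 for genes of 1191 to 13218 bases against exponential phase, and -0.08 and 0.29 against stationary phase. In stationary against exponential phase the same length classes had medians of -0.06 and -0.08.

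Neighbouring genes on 1 strand changed together, and shared transcripts (operons) may be the reason. Position along the contig alone would affect neighbours on opposite strands alike. At gaps of 0 to 300 bases, Spearman's rho between the fold changes of neighbours was 0.762, 0.708 and 0.691 on the same strand (2298 pairs) in the 3 comparisons. On opposite strands (473 pairs) it was 0.357, 0.380 and 0.373. The smallest of the 3 differences was 0.317 (bootstrap interval 0.234 to 0.407). The bootstrap drew pairs as independent units, although pairs share genes and neighbours change together. This interval and those below may therefore be too narrow. Reads shared between adjacent genes were tested with genes 1 gene apart, 600 to 3000 bases from each other, where the smallest difference was 0.284 (0.200 to 0.366). A first form of that test, on neighbours more than 300 bases apart, decided nothing, with differences of 0.06, -0.05 and -0.07 whose intervals include 0, as separate transcripts would also give. These values argue against position and shared reads as the whole cause; where transcripts begin and end was not measured, so operons remain a hypothesis.

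The 3 counts of changed genes were compared with other splits of the libraries into groups of the same sizes. There were 100 splits each, the real one included, of 1716, 792 and 462 possible. The smallest share this can give is 1 of 100, and it assumes independent libraries, which the labels do not state. Other splits also mix stages within groups, which widens the spread there, and their median count was 0 in each comparison. Chance is therefore not excluded. For stationary against exponential phase, 1 of 100 splits gave as many genes, the real one with 2492. The highest other, 1589, exchanged exponential replicates 1 and 2 with stationary replicates 5 and 6, which leaves 5 of 7 exponential and 4 of 6 stationary libraries in their own group. It also puts the 2023 libraries of both stages in 1 group, and whether its genes come from the stage or from the batch was not tested. For germination against exponential phase it was 1 of 100 with 2464, and 96 in the highest other split. For germination against stationary phase it was 1 of 100 with 2431, and 95 in the highest other.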
